A study of Bacillus subtilis with 8 samples.

How the data were processed

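RNA of Bacillus subtilis spores was sequenced in 8 libraries, 2 for each combination of strain (S-2 or 312) and treatment (mock or L-alanine), and each library was placed in its group by its strain and agent labels. Per the labels' protocols, total RNA was taken with TRIzol, ribosomal RNA was removed with a Ribo-Zero kit, the RNA was fragmented to 200 to 300 bp and reverse transcribed with random primers, and the libraries were sequenced on a HiSeq instrument. The molecule label reads polyA RNA, while the protocol describes ribosomal RNA removal. The table the authors deposited holds whole-number read counts per gene, not normalised, under a header that names them read counts, written with commas between groups of digits, which were removed. Per the submitters' processing notes, cutadapt, Bowtie2, Bowtie and DESeq 1.18.0 were named without their roles. The counter, the genome build, the annotation and the use of strand are not given in the sources used here. The table lists 4237 protein-coding genes by locus tag, and all 4237 matched the RefSeq table of assembly ASM904v1 (strain 168), which was used for symbols and coding lengths only. It also has 1 unnamed row holding the totals of the 4 S-2 libraries, each equal to the sum of its genes, which was left out of library sizes and tests. Paralogs such as fabHA and fabHB, the ssp genes or the long pks genes can share reads, and overlapping or antisense genes cannot be told apart without the strand, so values for such genes are uncertain. A strain can also differ in sequence from the reference, which lowers the counts of divergent genes.

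Library sizes were scaled with own code for the trimmed mean of M values (TMM, trims of 0.3 and 0.05), and normalised CPM are counts per 1e6 reads of the scaled library. The TMM factor of S-2 mock replicate 1 was 0.399, against 1.01 to 1.31 in the other libraries. Scaling by library totals instead shifted the median log2 fold change by 0.75 in the S-2 response, −0.22 in the 312 response, −0.75 and 0.22 between strains in mock and L-alanine spores, and 0.97 in the difference of responses, and directions are given relative to TMM. Genes were kept with a CPM equal to at least 10 counts at the median library size in 2 or more libraries and 15 counts in total, which left 3686. The tests were limma-voom with robust empirical Bayes (R 4.3.3, limma 3.58.1, statmod 1.5.0), 1 mean per group over all 8 libraries, contrasts of group means, 4 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05 with no minimum fold. Values are means ± SD of normalised CPM over 2 libraries, and log2 fold changes of genes are given with the SE of the model. For a list median, ± is an approximate SE from the spread over its genes. It treats genes as independent and holds no spread between libraries. A gene at 0 in both libraries of a group was given a bound against 3 counts over the group, since its fitted value depends on the prior count; intervals and floors cover counting error only. Shares of counts have exact Clopper-Pearson 95% intervals.

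The plan made before the data were examined was a quasi-likelihood count test from edgeR, which was not used, because the comma-formatted counts did not qualify for that tool in the format check; limma-voom took its place, chosen before any result. Quality weights and limma-trend were tried after results had been seen, so 3 kinds of fit were looked at, and the limma-voom one is the main one throughout. Of the other settings in the plan, the median-of-ratios and library-total scalings, no filter beyond 1 count, a mean count of at least 50, an adjusted p under 0.01, an absolute log2 fold change of at least 1, only the 2 groups compared, the replicate number as a block, leaving out each library, and leaving out genes at 0 in 1 strain were run.

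A total of 30 gene lists from textbook biology, fixed in advance, were tested with camera at a preset correlation of 0.01 and adjusted over 29 lists in each comparison; SP-beta prophage had 0 tested genes. The symbols epsJ and epsK each matched 2 loci, and both loci were kept in the biofilm list. With an estimated correlation 0 of 29 lists passed in each of the 5 comparisons, the smallest adjusted p-values being 0.24, 0.66, 0.25, 0.58 and 0.31. The lists of flagella, biofilm and coat genes stood for vegetative cells and mother cells that a spore preparation could hold. Genes named were, for each pairwise comparison, the 8 largest rises and 8 largest falls among called genes with a symbol, mean expression at or above the median and no overlap between replicates, up to 3 called members of each list that passed or was in question, or the 2 most abundant members of a list in question without a call; for the difference of responses, the 5 largest in each direction. The text names fewer than the rule allows, and lists the genes outside it as chosen after their values were seen.

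The code was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed by 2, 4 or 16-fold in each of 5 simulations and 3651 to 3684 genes tested. With the same spread in every group (SD 0.598 on the log2 scale), 16-fold changes were recovered in 99.1% of cases for both responses, 98.2% and 99.1% between strains in mock and L-alanine spores, and 84.7% for the difference of responses; 4-fold changes in 52.3%, 54.5%, 46.4%, 58.4% and 12.6%; and 2-fold changes in 5.99%, 5.71%, 5.71%, 3.61% and 0.300%. False calls were 5.30%, 4.38%, 4.60%, 4.32% and 3.61% of calls. With each group's own spread, recovery at 16-fold was 53.7%, 58.1%, 52.6%, 51.1% and 0.917%, and at 4-fold 8.68%, 0.601%, 7.27%, 0% and 0%. False calls were then 46 of 252 in the S-2 response and 37 of 240 between strains in mock spores, and 0 of 192, 168 and 3 in the 312 response, between strains in L-alanine spores and in the difference. In these simulations a single estimate of spread over 8 libraries was thus too small for the S-2 response and for the strains in mock spores, while the 3 calls in the difference are too few to say, and a gene not called here may have changed by 4-fold or more.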

Results

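Spores of Bacillus subtilis, a bacterium whose dormant spores can return to growth when they sense germinants such as the amino acid L-alanine, were profiled by RNA sequencing after removal of ribosomal RNA. Strains labelled S-2 and 312, both given as wild type, were each mock treated or treated with L-alanine, which gave 4 groups of 2 libraries. The deposited read counts for 4237 protein-coding genes summed to 11145599 and 10718046 in S-2 mock and 11524794 and 11595153 in S-2 L-alanine. In 312 they summed to 9628303 and 9396069 in mock and 9763754 and 8391236 in L-alanine libraries. Between 3654 and 3817 genes had at least 1 read in a library, and a floor of 3 counts stood at 0.199 to 0.674 normalised CPM, depending on the library. The labels do not say that the duplicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The growth protocol is worded alike for all 8 samples and places the spores in 100 mM L-alanine with 50 mM Tris-HCl, so what the mock samples received rests on the treatment label alone. The time between treatment and RNA extraction is not given in the sources used here.

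The 2 mock libraries of S-2 differed from each other far more than any other pair. Their log2 CPM correlated across genes at r = 0.816, against 0.966 to 0.991 in the other 3 groups. Of 3686 tested genes 1187 were over 4-fold apart, against 25 to 162. The SD of a replicate was 1.51 on the log2 scale, against 0.319 to 0.634. In S-2 mock replicate 1 the 10 most abundant genes held 33.8% of the counts (exact 95% interval 33.76 to 33.81%). hmpA, the flavohaemoglobin that detoxifies nitric oxide, held 8.20% (8.18 to 8.22%), against 0.0373% (0.0361 to 0.0384%) in replicate 2. The nitrate reductase gene narG, named after its values were seen, held 3.03% (3.02 to 3.04%) in replicate 1 and 0.0344% (0.0333 to 0.0356%) in replicate 2. Across gene lists, flagella and chemotaxis had a median log2 difference of 2.40 and iron starvation of 2.74 towards replicate 1. By contrast purine and pyrimidine synthesis had medians of −3.56 and −3.52, towards replicate 2. Every comparison with S-2 mock carries this difference.

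**Figure D1:**
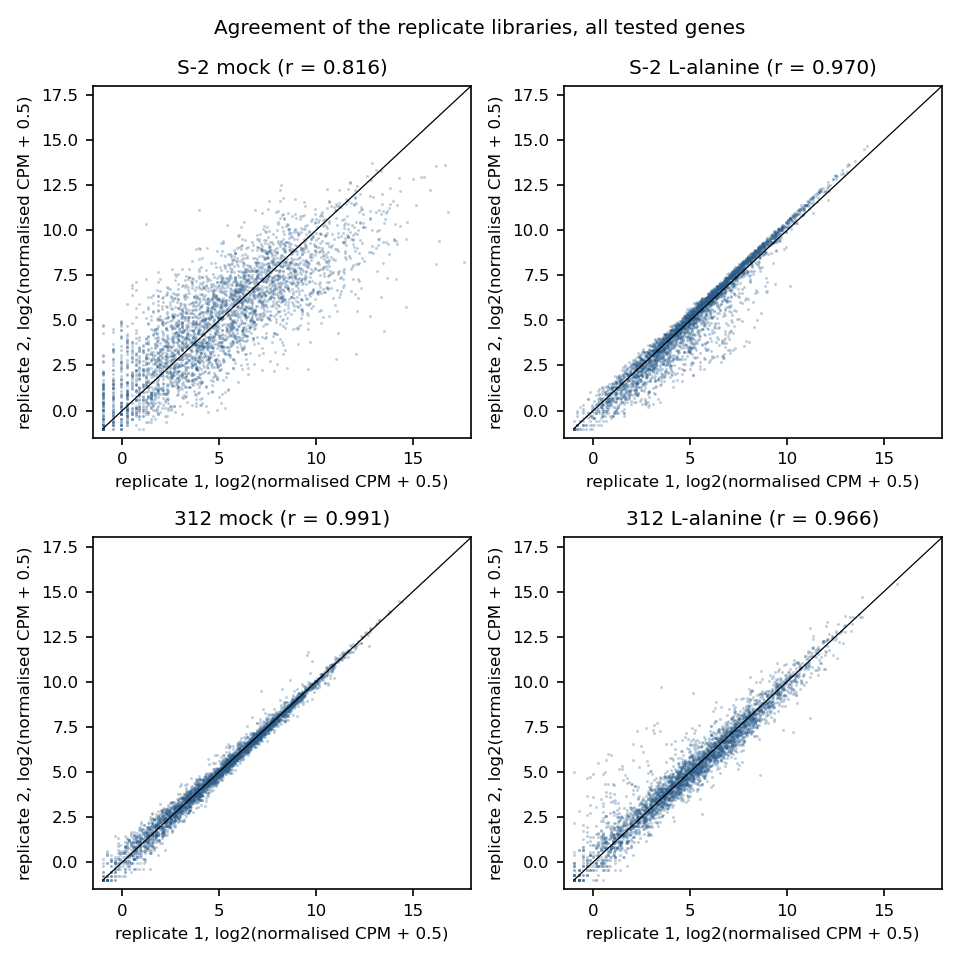
Replicate 1 against replicate 2 of each group, as log2 of normalised CPM plus 0.5 on both axes, 1 point per tested gene, with the line of equality in black. The S-2 mock libraries scatter widely (r = 0.816), and the other 3 groups lie close to the line (r = 0.966 to 0.991).

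The first question was what changed with L-alanine in S-2 spores. Of 13 measured genes of fatty acid and phospholipid synthesis 4 fell, 0 rose and 9 did not pass over all genes. Adjusted over the list alone 7 were lower, with a median log2 fold change of −2.75. The largest fall was in fabHB, 1 of the paired enzymes that start fatty acid chains, from 533 ± 76.2 to 9.01 ± 1.30 normalised CPM (SD, n = 2), a log2 fold change of −5.88 ± 0.38 (SE, limma-voom with Benjamini-Hochberg adjustment, adjusted p = 0.0060). Its partner fabHA fell from 991 ± 340 to 94.4 ± 12.4 CPM. plsX, which acts in phospholipid synthesis, fell from 725 ± 227 to 81.3 ± 9.11 CPM, and fabF, a chain-elongation enzyme, from 3204 ± 464 to 477 ± 31.6 CPM. As a set the list was lower than other genes (camera adjusted p = 6.6e-07; adjusted p = 0.43 with an estimated correlation). Without S-2 mock replicate 1 its median was −3.54 with 11 genes lower, and without replicate 2 it was −1.79 with 8 lower.

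Of 35 measured spore coat and crust genes, which the mother cell transcribes while a spore forms, 3 rose with L-alanine in S-2, 0 fell and 32 did not pass over all genes. Adjusted over the list alone 18 rose, 34 had a positive estimate and the median log2 fold change was 3.79. The crust genes cotZ, cotY and cotV rose by 8.13 ± 1.13, 8.01 ± 1.11 and 7.88 ± 0.98 on the log2 scale (SE, limma-voom adjusted p = 0.045, 0.045 and 0.036). Their levels differed between the L-alanine libraries: cotY stood at 664 and 127 CPM there, and at 0.674 and 1.49 CPM in the mock libraries. The set passed camera (adjusted p = 1.9e-15; adjusted p = 0.43 with an estimated correlation). Without either S-2 mock library 15 members were called, and the median was 3.75 or 3.74. The list of calcium dipicolinate handling and cortex lysis mixes genes that act in germination with genes that act while a spore forms. It had a positive estimate for all 16 measured and a median of 2.01 (camera adjusted p = 0.00014, and 0.60 with an estimated correlation). The set did not pass without S-2 mock replicate 2 (adjusted p = 0.18), and its median over the mock mean was 2.70 and 1.26 in L-alanine replicates 1 and 2. By limma-voom 0 of these 16 passed over all genes, 6 were higher at an unadjusted p under 0.05, and 3 rose adjusted over the list alone. Among small acid-soluble proteins, some of which coat spore DNA, sspA rose from 1.80 ± 0.315 to 38.8 ± 15.2 CPM (log2 fold change 4.32 ± 0.50, limma-voom adjusted p = 0.032). The other 9 measured did not pass (list median 1.43, camera adjusted p = 0.056; median 2.11 with 0.032 without S-2 mock replicate 1, and 0.77 with 0.55 without replicate 2).

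Genes of the general stress regulon under sigma B were lower with L-alanine in S-2 as a set, with a negative estimate for 21 of 21, a median of −2.02 and a camera adjusted p of 5.0e-13 (adjusted p = 0.24 with an estimated correlation). By limma-voom 0 of them passed over all genes, 20 were lower at an unadjusted p under 0.05 (1 was called by limma-trend and 0 with quality weights), and 20 fell adjusted over the list alone. Ribosomal protein genes had a median of −0.81 (50 measured, camera adjusted p = 4.6e-08; 0.43 with an estimated correlation). Biofilm matrix genes had one of −1.52 (23 measured, camera adjusted p = 2.0e-05; 0.43 with an estimated correlation; 0.059 without S-2 mock replicate 2). Other sets also passed camera on the lower side: branched-chain amino acid synthesis (median −1.52), secondary metabolites (−0.79), the tricarboxylic acid cycle (−0.73), iron starvation (−1.40) and translation factors with aminoacyl-tRNA synthetases (−0.29, but 0.46 and a camera adjusted p of 0.26 when scaled by library totals, and 0.055 with the replicate number as a block). By limma-voom 0 genes of these 7 lists passed over all genes, while 20, 10, 5, 4, 4, 5 and 3 were lower at an unadjusted p under 0.05 in the order given. Quality weights called 0 of them, and limma-trend 1 in the biofilm list; 9 biofilm and 1 iron starvation gene fell adjusted over the list alone. With an estimated correlation the adjusted p-values of the last 5 were 0.43 to 0.74, and iron starvation had a median of −0.03 without S-2 mock replicate 1 (camera adjusted p = 0.84). Secondary metabolites did not pass without replicate 1 (0.45), translation factors without replicate 2 (0.81) and the tricarboxylic acid cycle without replicate 1 or without replicate 2 (0.060 and 0.055). Branched-chain synthesis had medians of −0.95 and −2.14 without S-2 mock replicate 1 or 2. Without them 18 and 16 general stress genes and 36 and 14 ribosomal ones were called lower. Scaled by library totals the medians of ribosomal, tricarboxylic acid cycle and secondary metabolite genes were −0.07, −0.01 and −0.02. Pyrimidine synthesis did not pass (median 1.57, camera adjusted p = 0.056), with medians of −0.54 and 3.28 without S-2 mock replicate 1 or 2. Outside the lists, mtlA, the mannitol uptake permease, rose from 27.6 ± 10.5 to 1377 ± 362 CPM (log2 fold change 5.62 ± 0.49, limma-voom adjusted p = 0.014). cutR rose by 4.63, yisQ by 4.56 and glcD, a glycolate oxidase subunit, by 3.73 on the log2 scale. yplQ fell by 3.29 and azoJ by 2.82. Of the 18 measured genes for germinant receptors and their helpers 0 passed by limma-voom (3 higher and 1 lower at an unadjusted p under 0.05, 0 with quality weights or limma-trend), with a list median of 0.52 (camera adjusted p = 0.21; median 1.16 without S-2 mock replicate 2). Among them lgt, which modifies lipoproteins, stood at 187 ± 32.7 CPM in mock and 362 ± 83.1 CPM in L-alanine spores. The alanine dehydrogenase gene ald stood at 519 ± 286 and 583 ± 160 CPM, within the spread of replicates. The 6 genes of alanine metabolism had a median of 0.14 (camera adjusted p = 0.61), and 0.52 and −0.13 without S-2 mock replicate 1 or 2.

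Over all 3686 genes, limma-voom with Benjamini-Hochberg adjustment called 19 in S-2, 13 higher and 6 lower, and 735 had an unadjusted p under 0.05; scaled by library totals the calls were 25 higher and 0 lower. The count was 1437 without S-2 mock replicate 1, 1372 without replicate 2, 1 with quality weights and 0 (312 unadjusted) when only the 4 S-2 libraries were fitted. Against both mock libraries in turn 159 genes were called higher and 207 lower, while 270 were called in opposite directions, against 101, 171 and 265 if the calls were independent. Both fits use the same L-alanine libraries, which alone makes shared calls more frequent. limma-voom called 46 genes without S-2 L-alanine replicate 2, and 0 without replicate 1 or without any 1 library of 312 (358 to 627 unadjusted). In simulated data with each group's own spread 18.3% of the calls in this comparison were false, because the shared estimate of the spread lies below that of S-2 mock.

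**Figure D2:**
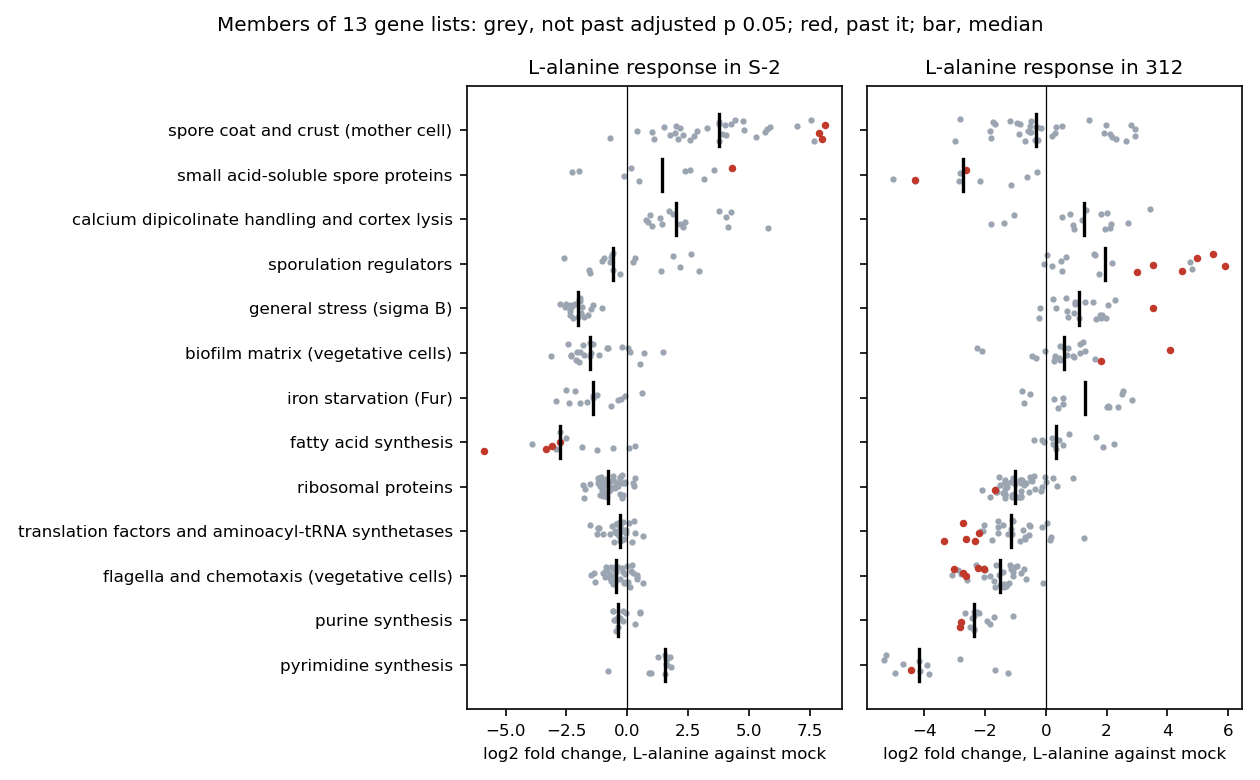
Log2 fold change with L-alanine of each measured member (points) of 13 gene lists in S-2 (left) and 312 (right); red points passed an adjusted p of 0.05, grey ones did not, and black bars are list medians. Coat genes have a median of 3.79 in S-2 and −0.32 in 312, and general stress genes medians of −2.02 and 1.09.

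The same question was asked in 312. Of 18 measured regulators of sporulation 6 rose with L-alanine, 0 fell and 12 did not pass, with 10 higher adjusted over the list alone and a median log2 fold change of 1.96 (camera adjusted p = 1.3e-06; 0.66 with an estimated correlation). sigE, the first mother-cell sigma factor, rose from 0.885 ± 0.350 to 58.0 ± 31.1 CPM (SD, n = 2), a log2 fold change of 5.90 ± 0.60 (SE, limma-voom adjusted p = 0.023). Its processing protease spoIIGA rose from 2.05 ± 0.188 to 99.5 ± 44.9 CPM. spoIIE, the phosphatase that activates the forespore sigma factor, rose from 13.4 ± 0.541 to 439 ± 195 CPM. racA, which anchors the chromosome at the cell pole during sporulation, rose by 4.64 ± 0.63 and ggt, which encodes gamma-glutamyltranspeptidase, by 4.40 ± 0.64 on the log2 scale. Large rises among abundant called genes were in ywmD (28.8 ± 0.114 to 3259 ± 877 CPM), ylaE (17.3 ± 1.11 to 1255 ± 124 CPM) and ywhL (29.9 to 1613 ± 446 CPM). Fitted rises in hmpA and ykjA were larger than those of ywmD and ylaE, at 8.97 and 10.28 on the log2 scale. General stress genes were higher as a set, with 19 of 21 positive, a median of 1.09 and a camera adjusted p of 5.9e-05 (0.66 with an estimated correlation). In this list csbA rose from 2.40 ± 0.429 to 29.6 ± 12.0 CPM and 9 rose adjusted over the list alone. Of 23 biofilm matrix genes 2 rose, epsD among them (1.82 ± 0.37), with 3 higher and 1 lower adjusted over the list alone. Their median was 0.61 (camera adjusted p = 0.026; 0.73 with an estimated correlation), and the set did not pass when scaled by library totals (0.078) or with the replicate number as a block (0.056). Over the mock mean their median was 0.33 and 0.91 in L-alanine replicates 1 and 2.

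On the lower side in 312, pyrimidine synthesis had a median of −4.16, and of −3.10 and −5.05 over the mock mean in L-alanine replicates 1 and 2. All 12 measured genes had a negative estimate. Of these 1 fell over all genes and 10 adjusted over the list alone (camera adjusted p = 1.1e-05; 0.66 with an estimated correlation). That gene, pyrG, the CTP synthase, fell from 990 ± 239 to 46.9 ± 18.6 CPM. In purine synthesis 2 of 15 fell, with a median of −2.36 (camera adjusted p = 2.9e-05; 0.66 with an estimated correlation). guaB fell from 878 to 125 ± 29.6 CPM and guaA from 1146 ± 21.6 to 167 ± 10.8 CPM, both enzymes of GMP synthesis. Translation factors and aminoacyl-tRNA synthetases had 5 of 31 lower, a median of −1.13 and 8 lower adjusted over the list alone. alaS, hisS and thrS were lower, with log2 fold changes of −3.36, −2.74 and −2.61. In ribosomal proteins 1 of 50 fell, rplO at −1.67 ± 0.36, with a median of −0.996. In flagella and chemotaxis 5 of 37 fell, and 10 adjusted over the list alone, with a median of −1.496. Of these cheD, the motility sigma factor sigD and the flagellin export chaperone fliT fell by 3.03, 2.72 and 2.63 on the log2 scale. These 3 sets passed camera (adjusted p = 1.0e-06, 1.4e-08 and 5.4e-08) and had adjusted p-values of 0.66 with an estimated correlation. Small acid-soluble proteins had a median of −2.71 (2 of 10 lower, 4 adjusted over the list alone, camera adjusted p = 0.00045; 0.66 with an estimated correlation). sspA fell from 14.9 ± 1.47 to 2.38 ± 0.0188 CPM. Glycolysis and glucose uptake had a median of −1.23 (camera adjusted p = 0.0037; 0.66 with an estimated correlation). By tool, 0 of its 12 genes passed by limma-voom or limma-trend, 3 were lower at an unadjusted p under 0.05 and 11 were called lower with quality weights. Other falls were in rocA, of arginine catabolism (178 ± 3.19 to 8.68 ± 4.40 CPM), yxaH, nupN, the antimicrobial-peptide transporter genes psdA and psdB (−3.69 and −3.54), and srfAC, of surfactin synthesis (10294 ± 947 to 821 ± 95.2 CPM). Germinant receptor genes had a median of 0.46 (camera adjusted p = 0.29), calcium dipicolinate and cortex genes of 1.255 (0.12) and alanine metabolism genes of 0.63 (0.97). Over the mock mean these 3 medians were 0.31, 0.38 and −0.14 in L-alanine replicate 1 and 0.91, 2.14 and 0.62 in replicate 2. By limma-voom 0 genes of these 3 lists passed; at an unadjusted p under 0.05 the lists had 3 higher, 4 higher, and 1 higher with 1 lower, and with quality weights 6 higher with 1 lower, 4 higher, and 2 higher with 1 lower.

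The count for 312 was 205 genes, 125 higher and 80 lower, of 3686 tested (limma-voom, Benjamini-Hochberg), with 1007 at an unadjusted p under 0.05. It was 1620 and 1641 without S-2 mock replicate 1 or 2, 1741 with only the 4 libraries of 312, 1775 with quality weights and 105 when scaled by library totals. Without any 1 of the other 6 libraries it was 0, with 472 to 847 genes at an unadjusted p under 0.05.

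**Figure D3:**
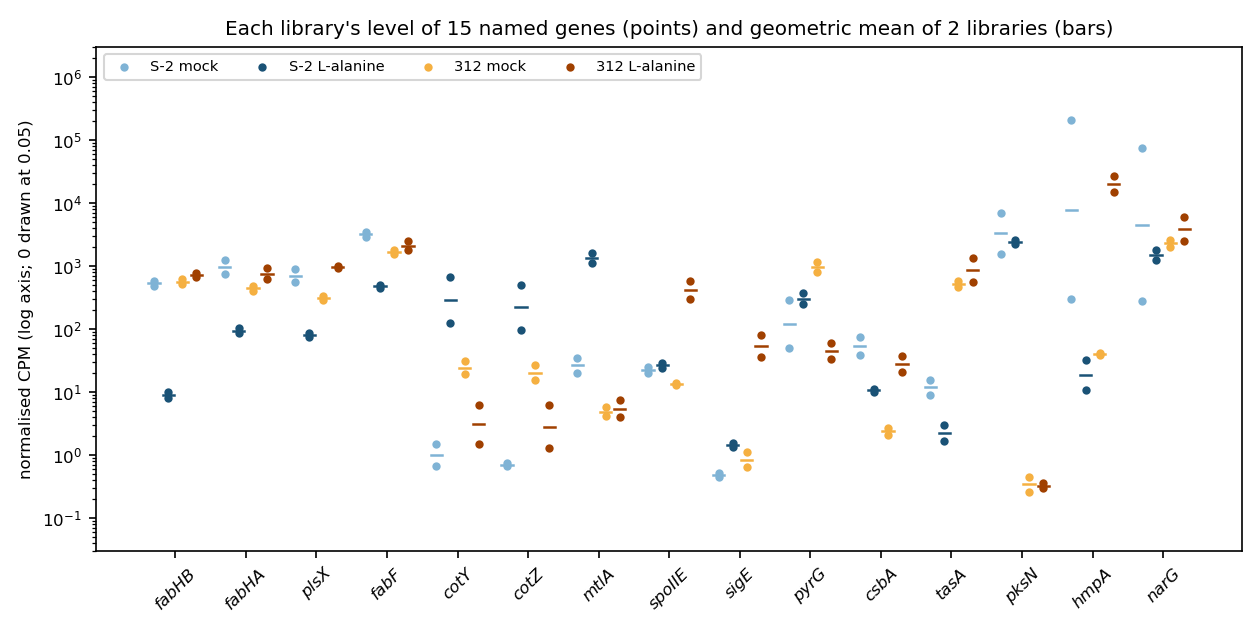
Normalised CPM on a log axis of 15 genes in each of the 8 libraries (points), coloured by group, with the geometric mean of 2 libraries as bars; narG was added after its values were seen. fabHB is at 9.01 CPM in S-2 L-alanine spores and at 533 to 721 CPM on average in the other groups, and hmpA is at 205370 CPM in S-2 mock replicate 1 and 299 CPM in replicate 2.

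Mock-treated spores of the strains were compared next. Genes of the biofilm matrix were lower in S-2, 20 of 23 measured, with 0 higher and a median log2 difference (S-2 against 312) of −4.01 (camera adjusted p = 8.1e-14; 0.25 with an estimated correlation). tasA, the matrix fibre protein, was at 12.3 ± 4.78 CPM in S-2 and 523 ± 74.4 CPM in 312 (SD, n = 2), a difference of −5.51 ± 0.59 (SE, limma-voom adjusted p = 0.0013). General stress genes were higher in S-2, 12 of 21 with 0 lower and a median of 2.65 (camera adjusted p = 3.9e-09; 0.25 with an estimated correlation). csbA was at 57.5 ± 26.7 against 2.40 ± 0.429 CPM and ydaD was higher by 4.39 ± 0.75 on the log2 scale. gtaB, of the same list, was at 1192 ± 1310 CPM in S-2 and 0.178 ± 0.0055 CPM in 312. The 312 value lies below the floor of 3 counts in each 312 mock library (0.261 and 0.273 CPM). Lower expression of gtaB in 312 thus cannot be told from absence there or from divergence from the reference. Competence genes were lower in S-2 (7 of 17, median −2.81, camera adjusted p = 0.00020; 0.35 with an estimated correlation). Among them were comGA and comGB of the DNA uptake machinery, at −4.53 and −4.59. Small acid-soluble protein genes were lower by camera (3 of 10 called, median −2.97, camera adjusted p = 0.00076; 0.73 with an estimated correlation; 0.057 without S-2 mock replicate 2). sspE was at 62.0 ± 65.1 against 1826 ± 1541 CPM. Genes of the defective prophage PBSX were higher by camera (5 of 21 called, median 1.82, camera adjusted p = 9.4e-05), as were those of arginine synthesis (1 of 9, argF, median 2.11, adjusted p = 0.0025; 0.073 without S-2 mock replicate 2). Translation factors with aminoacyl-tRNA synthetases were lower by camera (1 of 31 called, thrS, median −0.72, adjusted p = 0.0095; 0.068 without S-2 mock replicate 1). With an estimated correlation these 3 sets had an adjusted p of 0.91. Of 30 matched PBSX genes 7 had 0 counts in all 4 libraries of 312, against 1 in all 4 of S-2, so absent or divergent sequence can add to the PBSX difference. Adjusted over the list alone the calls in these 7 lists, in the order given, were 20, 17, 10, 7, 10, 6 and 0. Without S-2 mock replicate 1 or 2, 20 and 15 general stress genes, 8 and 17 PBSX genes and 9 and 5 arginine genes were higher, and 6 and 4 small acid-soluble and 5 and 21 translation genes lower. The medians were then −1.85 and −2.96 for competence, 1.205 and 2.97 for PBSX, 3.23 and 1.02 for arginine and −0.20 and −1.22 for translation. Of 37 flagella and chemotaxis genes 9 were lower and 0 higher, with a median of −0.13 (camera adjusted p = 0.21). Without replicate 1 it was −1.42 with 22 lower and 2 higher (5.0e-07), and without replicate 2 it was 1.11 with 21 higher and 10 lower (0.057).

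Among single genes in mock spores, pksN and pksR, of bacillaene synthesis, were at 4276 ± 3854 and 4266 ± 4594 CPM in S-2 and at 0.358 ± 0.137 and 0.406 ± 0.328 CPM in 312. Also higher in S-2 were yvaM (8.25 ± 0.48), the oligopeptide permease gene appC (6.77 ± 0.51), the phosphatase gene rapH (6.58 ± 0.76), ydbD (6.65 ± 1.19) and yocB (6.37 ± 1.11). Lower in S-2 were psdA (−5.81 ± 0.68), the chemoreceptor gene tlpA (−5.70 ± 0.92), yfmS (−5.67 ± 0.61) and ylqB (−5.63 ± 0.64). Of 18 genes for germinant receptors and their helpers 3 were higher and 3 lower, with a median of −0.61 (camera adjusted p = 0.66), and 0.14 and −1.35 without S-2 mock replicate 1 or 2. The receptor homologues yfkT and yfkR had 0 counts in both S-2 mock libraries and were at 65.3 ± 27.7 and 11.5 ± 3.38 CPM in 312, at least 388-fold and 68.6-fold lower against a floor of 3 counts over the group. ald was at 519 ± 286 against 902 ± 146 CPM (−0.93 ± 0.66, limma-voom adjusted p = 0.38). A gene near 0 in 1 strain may be absent there or too different from the reference used for counting, which these counts do not separate. limma-voom called 498 of 3686 genes, 279 higher and 219 lower in S-2 (205 and 241 when scaled by library totals), with 1071 at an unadjusted p under 0.05. The count was 1077 and 2033 without S-2 mock replicate 1 or 2, 231 and 238 without 312 mock replicate 1 or 2, 203 with only the 4 mock libraries, 243 with quality weights, and 293 without genes at 0 in all 4 libraries of a strain. In simulated data with each group's own spread 15.4% of the calls in this comparison were false.

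The strains were also compared after L-alanine. Biofilm matrix genes were again lower in S-2, 21 of 23 with 1 higher and a median of −5.92 (camera adjusted p = 6.9e-13; 0.58 with an estimated correlation). tasA was at 2.34 ± 0.913 against 953 ± 549 CPM (SD, n = 2), and epsF, of the matrix polysaccharide operon, at 1.16 ± 0.0456 against 311 ± 12.8 CPM. Fatty acid synthesis genes were lower (8 of 13, median −3.23, camera adjusted p = 0.00025; 0.83 with an estimated correlation). fabHB differed by −6.32 ± 0.39 and fabI, an enoyl reductase, by −5.96 ± 0.82. Sporulation regulators were lower (11 of 18, median −2.10, camera adjusted p = 0.00028; 0.78 with an estimated correlation). sigE differed by −5.19 ± 0.59 and spoIIE by −3.97 ± 0.43. Coat genes were higher (15 of 35, 0 lower, median 2.82, camera adjusted p = 0.00034; 0.94 with an estimated correlation). In the coat list cotV and cotR had 0 counts in both 312 L-alanine libraries and were at 186 ± 171 and 79.1 ± 82.1 CPM in S-2. These means were at least 1143-fold and 486-fold higher against the floor, but the S-2 libraries were far apart (cotR at 2067 and 260 counts). Both genes were also hardly read in 312 mock spores, cotR at 0 counts and cotV at a mean of 0.0436 CPM. PBSX genes were higher (12 of 21, 1 lower, median 2.79, camera adjusted p = 0.00036). Of 30 matched PBSX genes 7 had 0 counts in all 4 libraries of 312, against 1 in all 4 of S-2. Sequence that is absent or divergent in 312 can thus add to this difference. Pyrimidine synthesis genes were also higher (4 of 12, median 4.06, camera adjusted p = 0.015, and 0.064 when scaled by library totals). pyrE was at 743 ± 6.03 against 28.0 ± 24.4 CPM. Competence genes (5 of 17, median −1.71, adjusted p = 0.021; 0.059 without S-2 mock replicate 2) and iron starvation genes (4 of 14 lower and 1 higher, median −2.60, adjusted p = 0.049) were lower. The last include dhbE and dhbF of bacillibactin synthesis, at −5.26 and −4.68. With an estimated correlation these 4 sets had adjusted p-values of 0.83 to 0.94. Adjusted over the list alone the calls in the named direction were 21, 10, 12, 21, 13, 9, 5 and 4, in the order given. Of 37 flagella and chemotaxis genes 4 were higher and 7 lower, with a median of 1.76 (camera adjusted p = 0.32; 0.035 when scaled by library totals, and 0.011 and 0.012 without S-2 mock replicate 1 or 2).

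Among single genes after L-alanine, mtlA was at 1377 ± 362 against 5.76 ± 2.45 CPM and mtlD, mannitol-phosphate dehydrogenase, at 3200 ± 894 against 24.3 ± 5.50 CPM. bglP and bglH, for uptake and cleavage of beta-glucosides, were higher by 7.20 ± 1.12 and 7.27 ± 1.52 on the log2 scale. The magnesium transporter gene mgtE was at 2054 ± 304 against 17.8 ± 4.30 CPM. Higher in 312 were hmpA (20987 ± 8475 against 21.5 ± 15.2 CPM), nasD, of nitrite reductase (13216 ± 1023 against 67.8 ± 9.78 CPM), ykjA, ywmD and yitM. Of the germinant receptor list 3 were higher and 4 lower in S-2 (median −0.20, camera adjusted p = 0.58), lgt at 2.25 among those higher. Small acid-soluble proteins had 3 higher, sspA among them (3.94 ± 0.49), and 1 lower (median 1.11, camera adjusted p = 0.56). The calcium dipicolinate and cortex list had 2 higher, with the cortex hydrolase gene cwlJ at 35.3 ± 30.7 against 3.04 ± 0.903 CPM (median 0.08, camera adjusted p = 0.62). ald was at 583 ± 160 against 522 ± 364 CPM. In all, limma-voom called 1008 of 3686 genes, 525 higher and 483 lower in S-2, with 1503 at an unadjusted p under 0.05. The count was 2198 and 2202 without S-2 mock replicate 1 or 2, 1894 with only the 4 L-alanine libraries, and 2035 with quality weights. It was 445 and 527 without S-2 L-alanine replicate 1 or 2, 659 and 655 without 312 mock replicate 1 or 2, and 540 and 438 without 312 L-alanine replicate 1 or 2.

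Whether the strains responded differently was tested as the difference of their responses, S-2 minus 312. The fructose operon genes fruA, fruK and fruR had differences of 9.05 ± 1.79, 9.26 ± 2.06 and 8.53 ± 1.90 (log2, SE; limma-voom adjusted p = 0.037, 0.048 and 0.048). fruA was at 1871 ± 79.3 and 31.8 ± 1.37 CPM in mock and L-alanine spores of 312, and at 731 ± 924 and 2856 ± 735 CPM in those of S-2 (SD, n = 2). cgeB, of the spore surface, and sspE also had positive differences (7.92 ± 1.55 and 6.89 ± 1.37). hmpA, ykjA and nasD had the most negative ones (−17.85 ± 3.69, −16.72 ± 3.53 and −10.53 ± 1.95). These 3 were far apart in the S-2 mock libraries, with hmpA at 205370 and 299, ykjA at 2209 and 19.3, and nasD at 18722 and 613 CPM. ylaE and ywmD followed at −8.85 ± 0.99 and −8.46 ± 1.64. Of 29 lists 13 differed between the strains by camera. General stress genes had a median difference of −3.45 with 12 of 21 genes called (adjusted p = 5.0e-11; 0.31 with an estimated correlation), coat genes of 3.46 with 8 of 35 (6.6e-07; 0.71). Fatty acid synthesis had one of −3.13 with 6 of 13 (4.4e-05; 0.67 with an estimated correlation) and pyrimidine synthesis of 5.76 with 1 of 12 (4.4e-05; 0.71 with an estimated correlation). Adjusted over the list alone 19, 12, 7 and 10 genes of these 4 lists passed. Over all genes 19, 11, 10 and 10 were called in the named direction without S-2 mock replicate 1 and 17, 14, 8 and 12 without replicate 2. Across 3686 genes the responses of the strains correlated at Pearson r = −0.166 and Spearman rho = −0.133, and 1709 genes (46.4%) had the same direction. Genes are not independent replicates, and without S-2 mock replicate 1 r was 0.0470. 2 genes were called in both strains. limma-voom called 277 genes for the difference, 111 positive and 166 negative (69 and 41 when scaled by library totals), with 991 at an unadjusted p under 0.05. The count was 1402 and 1744 without S-2 mock replicate 1 or 2, 161 with quality weights, 14 without S-2 L-alanine replicate 2, and 0 without any 1 of the other 5 libraries (602 to 756 unadjusted).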

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

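The differences of responses were planned; of the tests of explanations below, those on coding length and on mother-cell genes were set before their results were seen, and the others after. Groups of 2 libraries are too small to test a single library for standing apart. What drew attention is that the response to L-alanine differed between S-2 and 312, by the test of the difference itself, for 44 of the named genes and 13 lists. Because genes were named for large changes, 10 of them for a large called difference, the number 44 was partly fixed by that choice. Over all genes 277 of 3686 were called for the difference. Of the 44 genes 39 had fitted responses of opposite direction, while over all 3686 tested genes 46.4% had the same direction. Keeping genes whose difference passed favours opposite directions. All differences are log2 fold changes of S-2 minus those of 312, with limma-voom adjusted p-values of 0.025 to 0.049 for the genes. None of these calls held without any 1 of the 4 libraries of 312 or without S-2 L-alanine replicate 1, where limma-voom called 0 genes (602 to 756 at an unadjusted p under 0.05).

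On the positive side were the coat and crust genes cotY (10.99), cotZ (10.95), cotV (8.38) and cgeB (7.92), where cotV had 1 count in 312 mock and 0 in 312 L-alanine spores, so that its value depends on the prior count. The fructose genes fruK (9.26), fruA (9.05) and fruR (8.53), the small acid-soluble protein genes sspA (6.93) and sspE (6.89), and the transport genes mgtE (5.65) and mtlA (5.45) were also positive. So were pyrG (5.70), yisQ (5.23), cutR (5.08), rocA (5.02), psdA (4.80), psdB (4.61), alaS (4.01), yxaH (3.99), glcD (3.93), guaB (3.36) and guaA (2.62). On the negative side were hmpA (−17.85), ykjA (−16.72) and nasD (−10.53), ylaE (−8.85) and ywmD (−8.46), the fatty acid and phospholipid genes fabHB (−6.23), fabI (−6.18), plsX (−4.75), fabHA (−4.11) and fabF (−3.05), and the sporulation genes racA (−5.65), spoIIE (−4.71) and sigE (−4.52). The rest were yplQ (−6.27), yitM (−6.11), csbA (−5.86), dhbF (−5.00), ggt (−4.63), azoJ (−4.08), yvaM (−3.92), epsD (−3.90) and epsF (−3.09).

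By camera the lists with a positive median difference were pyrimidine synthesis (5.76), small acid-soluble spore proteins (3.46), coat and crust (3.46), purine synthesis (1.84), flagella and chemotaxis (1.22) and translation factors with aminoacyl-tRNA synthetases (0.81). Those with a negative one were secondary metabolites (−0.95, but 0.13 when scaled by library totals), arginine synthesis (−1.89), iron starvation (−2.33), biofilm matrix (−2.40), sporulation regulators (−2.58), fatty acid synthesis (−3.13) and general stress (−3.45). Their adjusted p-values ran from 5.0e-11 to 0.030 and were 0.31 to 0.71 with an estimated correlation. The median for flagella was −0.03 without S-2 mock replicate 2 and that for purines −0.06 without replicate 1; iron starvation, translation and purines did not pass without replicate 1 (camera adjusted p = 0.24, 0.21 and 0.37), and small acid-soluble proteins, flagella and arginine synthesis did not pass without replicate 2 (0.094, 0.55 and 0.38). Purine and arginine synthesis also did not pass when scaled by library totals (0.080 and 0.082). Of 36 matched secondary metabolite genes 8 had 0 counts in all 4 libraries of 312. Of these 5 had at least 10 counts in each S-2 library. For such genes the fitted response of 312 depends on the prior count, so this list's difference partly sets S-2 against genes not read in 312.

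The first pattern weighed is the difference between the S-2 mock libraries. Genes seen in all 312 libraries and in no S-2 L-alanine library reached at most 0.310% of their 312 level in an S-2 mock library (31 genes), which argues against reads of 312 in either. The best correlation of an S-2 mock with an S-2 L-alanine library was 0.882, below the 0.970 of the L-alanine pair, which argues against an L-alanine library under a mock label. With the 31 most abundant genes left out the replicate SD was still 1.502, against at most 0.635 elsewhere. An SD over genes ignores a shift common to all genes, and leaving out 31 of 3686 genes could hardly change it. This test therefore shows only that the scatter is not confined to these genes. It cannot decide on other effects of a few abundant genes. Coding length accounted for 0.379% of the variance of the difference, so a length bias does not account for it. The design names no group that separates these libraries, so no biological explanation from the design was tested.

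The second pattern is the positive median of the coat list with L-alanine in S-2. The list's median log2 fold change was at least 3.75 ± 0.49 under the other scalings and at least 3.74 ± 0.55 without either mock library. Library totals and median-of-ratios factors shift the S-2 response by a median of 0.75 and −0.04, so the first value followed from these shifts. They are too small to account for the list's median. The values without either mock library argue against a single mock library as the cause. A candidate explanation is more RNA of the mother cell in the L-alanine samples: 18 mother-cell genes outside the coat list had a median of 1.64 ± 0.24, above 99.95% of random lists of like expression, and 17 of them were positive. Some share an operon, such as the spoIIIA genes, while the random lists drew single genes, so the percentiles and ± values overstate the evidence in both strains. Others lay near the floor in S-2 mock, such as spoIIIAD at 0.225 and 0.374 CPM. In 312 the same 18 genes had 17 positive and a median of 2.0002 ± 0.27, above 100% of such random lists, while the coat list had one of −0.32; by library they stood above the mock mean in 17 cases in L-alanine replicate 2 (median 4.50) and in 9 in replicate 1 (0.02), and the coat genes in 17 and 11 of 35 (−0.07 and −0.63). In L-alanine replicate 2 of 312 the 18 genes stood higher while the coat list did not, so they need not track the source of coat RNA. That is 1 library of the other strain, which decides nothing for S-2. An effect of L-alanine within the spores was not tested apart from the candidate.

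The third pattern is the general stress list, with a negative median with L-alanine in S-2 and a positive one in 312. The median difference nearest 0 was −2.49 ± 0.30 under the other scalings and −3.16 ± 0.41 without 1 S-2 mock library. Library totals and median-of-ratios factors shift the difference of responses by a median of 0.97 and −0.03, so the first value followed from these shifts. They are too small to account for the list's difference, and a single mock library does not account for it. In mock spores the list stood higher in S-2 than in 312 (median 2.65, camera adjusted p = 3.9e-09; adjusted p = 0.25 with an estimated correlation), and whether these differences come from the strain or from how its spores were made was not tested.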

How the results depend on the processing

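Quality weights, limma-trend, and for gene lists all settings other than median-of-ratios scaling, the replicate block and the estimated correlation were chosen after seeing the data. Where no value below shows it, the cause was not tested. With 1 library of a group left out, the lone library is assumed to vary like the other groups. Named genes that were called kept their direction under every alternative in all 5 comparisons (222, 464, 442, 543 and 150 values), and kept the call in 89, 246, 368, 506 and 72 of these. The values are refits of the same genes and libraries. Because the genes were named for large called changes, in pairwise comparisons often without overlap between replicates, a kept direction was largely fixed by that choice.

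The L-alanine response in S-2 (19 calls) gave 1 call with quality weights, 30 with limma-trend, 0 with only the 2 groups compared (312 at an unadjusted p under 0.05) and 1 at an adjusted p under 0.01; with 1 library left out the calls ranged from 0 to 1437 (0 with 358 to 627 unadjusted). The L-alanine response in 312 (205) gave 105 by library totals, 1775 with quality weights, 1741 with only the 2 groups compared and 0 at an adjusted p under 0.01, and ranged from 0 to 1641 with 1 library left out; all 205 genes were among the 1775, 1620 and 1641 of the fits with quality weights or without an S-2 mock library. S-2 against 312, mock (498) gave 243 with quality weights, 203 with only the 2 groups compared, 293 without genes at 0 in 1 strain and 279 at an adjusted p under 0.01, and ranged from 231 to 2033. S-2 against 312, L-alanine (1008) gave 2035 with quality weights, 1894 with only the 2 groups compared and 515 at an adjusted p under 0.01, and ranged from 438 to 2202. The difference of L-alanine responses between strains (277) gave 110 by library totals, 161 with quality weights and 0 at an adjusted p under 0.01, and ranged from 0 to 1744. Leaving out either S-2 mock library, which removes the pair with the largest spread from the shared estimate, raised the count in all 5 comparisons.

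Deviations of same-numbered libraries correlated at −0.068 in S-2 and 0.027 in 312, which gave no sign of pairing but does not show that the samples are unpaired. The sample titles share these numbers between mock and L-alanine libraries, and the labels do not state a pairing. With the replicate number as a block, limma-voom called 0 genes in the L-alanine response in S-2, 0 in that of 312 and 0 in the difference of responses (569, 843 and 819 at an unadjusted p under 0.05), 414 between strains in mock and 841 in L-alanine spores; the block takes up residual degrees of freedom.

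The correlation of L-alanine responses between strains (−0.166) ranged from −0.320 without S-2 mock replicate 2 to 0.0470 without replicate 1 with 1 library left out, and from −0.188 to −0.141 under the other settings. Gene lists passing camera numbered 11, 10, 7, 8 and 13 in the 5 comparisons and 0 in each with an estimated correlation; with 1 library left out they ranged from 9 to 17, 9 to 12, 7 to 11, 6 to 12 and 10 to 14, and lists between strains in L-alanine spores numbered 5 with a mean count of at least 50. Among uncalled genes, for ald, L-alanine response in S-2, the log2 fold change went to −0.42 without S-2 mock replicate 1 and to 0.97 without replicate 2. For ald, S-2 against 312, L-alanine, it went to −0.30 without 312 L-alanine replicate 1 and 1.12 without replicate 2. For lgt, L-alanine response in 312, the log2 fold change went to −0.48 without 312 L-alanine replicate 1 and 0.00793 without replicate 2. Median-of-ratios scaling, no filter, and an absolute log2 fold change of at least 1 left each count of called genes within 1.5 times.

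The planned DESeq2 Wald test was not run: the values are whole-number counts, but with their commas they did not pass the format check set for count tools. Keeping ribosomal and transfer RNA genes had nothing to act on, since the table lists protein-coding genes, and the alternatives for normalised values did not apply to read counts. Depth limits genes near the floor of 0.199 to 0.674 CPM, such as cotZ in S-2 mock spores (0.711 CPM).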

Other observations

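The genes and the hypothesis in this part were chosen after the values were seen, and its test was too. Some genes were read in 1 strain only: 81 had 0 counts in all 4 libraries of 312 and at least 10 in each of S-2, and 28 the reverse. Among the 81 were skfF and skfE of the sporulation killing factor operon (at least 391 and 259 counts in each S-2 library), bsuMA and bsuMB of a DNA methyltransferase (416 and 330), tcyJ and tcyK of a sulphur compound transporter (64 and 57), the wall polymer genes mnaA and tagD (478 and 154), pksB and pksC of bacillaene synthesis (134 and 114) and the coat gene cotR (40). Among the 28 were the mobile element genes immA, nicK and rapI (298, 548 and 447 counts summed over the 312 libraries) and yrkL (3876). Of 4237 genes 319 had 0 counts in all 8 libraries, among them 128 of the 129 SP-beta prophage genes. A count of 0 can reflect sequence that differs from the reference as well as absence.

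Lists that did not pass camera in any of the 5 comparisons included RNA polymerase and elongation factors (median log2 fold change −0.29 in the S-2 and −0.40 in the 312 response), ATP synthase (0.06 and −0.38), the respiratory chain (−0.11 and −0.20), cell division and wall synthesis (0.26 and 0.28), DNA replication (0.23 and −0.33), heat shock and protein quality control (0.03 and −0.55) and the DNA damage response (−0.63 and 0.08). Some S-2 medians near 0 averaged opposite results against the 2 mock libraries. Without S-2 mock replicate 1 or 2 the medians were −1.06 and 1.24 for ATP synthase (camera adjusted p = 0.0041 and 0.0018) and 1.07 and −1.15 for the respiratory chain (0.0011 and 0.00024), with 8 of 9 and 8 of 16 genes called in opposite directions. The same held for purine synthesis (−2.35 and 1.63) and flagella and chemotaxis (0.87 and −1.35), with 7 of 15 and 14 of 37 genes. Without S-2 mock replicate 1 RNA polymerase and heat shock genes had S-2 medians of −0.79 and −0.98, against −0.29 and 0.03 with both mock libraries, so these medians also depend on the mock library used.

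The difference between the S-2 mock libraries, replicate 1 minus 2, correlated across 3686 genes with the response of 312 to L-alanine, with which it shares no library (Pearson r = 0.311, Spearman rho = 0.299). A candidate explanation is that the cells or spores of S-2 mock replicate 1 were made with less oxygen. The 12 measured genes of a list of anaerobic growth had a median log2 difference of 4.62 ± 1.52 between the libraries, 11 of them higher in replicate 1, above 100% of random lists of like expression. That list holds genes already seen among the most abundant, narG among them (75899 and 276 CPM). The 5 genes outside the operons already seen had a median of 1.06 ± 2.47, at percentile 82.6; fnr stood at 4362 and 44.7 CPM and narK at 7016 and 37.1 CPM, while hemZ was lower in replicate 1 (−2.76). The median of these 5 lies within its spread, so the hypothesis cannot be told apart from other differences between the preparations. In the response of 312 to L-alanine the 12 genes had a median of 1.48 ± 0.66, 9 of them positive. The 5 genes had one of 1.59 ± 1.21, with 3 positive. Higher levels of the list were thus not particular to S-2 mock replicate 1.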
